A study of Homo sapiens with 4 samples.

How the data were processed

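RNA of ARP1 multiple myeloma cells was measured in 4 libraries, 2 of cells overexpressing RFWD2 (current symbol COP1) and 2 of wild type cells. Groups and replicate numbers were taken from the genotype and title given for each sample. Per the labels' protocols, total RNA was poly(A)-selected, fragmented, reverse-transcribed and sequenced as paired ends on an Illumina NovaSeq instrument. The same protocol text speaks of adipose material, which fits no other label of these samples. The samples' description fields read ARP1, ARP2, ARP3 and ARP4 in turn while the cell line field reads ARP1 for each, and whether the former are sample codes is not given in the sources used here.

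The deposited table gives, per gene, whole-number columns headed as counts and columns headed as FPKM, with 1 column of each per sample, per the file headers. The submitters' processing notes name HISAT2 2.0, StringTie 1.3.0, Bowtie 0.12.2 and the mouse build mm8, without saying what each was used for. The table itself holds 58825 human Ensembl gene identifiers and 0 mouse ones, of which 99.5% occur in GENCODE release 29 on GRCh38, 94.8% with the same chromosome, strand and at least 1 end. Coordinates are printed as the table gives them. The counting tool, its use of strand and the annotation release are not given in the sources used here. The deposited count columns were treated as estimated counts because their low values pile up on multiples of 4 (35.4% to 36.0% of the counts from 1 to 19 in each library). Their ratio to FPKM was fixed per gene, which plain read counts would give as well, and whether they are such is not given in the sources used here. The deposited FPKM columns hold 0.0001 as a placeholder, almost always where the count is 0, and this was set to 0. How reads shared by overlapping genes or near-identical copies were assigned is not given in the sources used here.

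Total estimated counts ran from 62143098 to 70713792 per library. With 2 libraries per group there are 6 assignments of libraries to groups, and an exact two-sided permutation test cannot go below p = 0.333, so none was used. The gene test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3) on the estimated counts, which were already whole numbers, with TMM factors, filterByExpr at its defaults, no block and Benjamini-Hochberg adjustment over 18873 genes. A gene was called at an adjusted p under 0.05, two-sided. The design foresaw limma on FPKM unless the table also held counts. The count columns, though treated as estimates, were taken to meet that condition, and limma (3.58.1) on log2(FPKM + 1) was run as the alternative. A divisor of 4 was among the alternatives because of the pile-up on multiples of 4. Within-number fold changes of genes are differences of log2 CPM with a prior count of 2.

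Gene lists were tested with camera in limma on log2(FPKM + 1) over 11229 genes with a mean of at least 1 FPKM, with the correlation between genes preset at 0.01, and adjusted over the 30 lists with at least 5 such members. The 8 lists of other cell types' markers had too few such members and were given as levels. All 1136 symbols of the 38 lists were found in the table. The groups, the tests, the lists, the alternatives and the rule for named genes were set before the data were examined, except alternatives described as chosen later. The rule names RFWD2, CDKN1B, RCHY1, JUN, PSMB5 and 1 more gene, which, like 1 of the tested lists, is not reported here. It adds the genes with the largest change in log2(FPKM + 1) among those called, up to 12 each way, if the libraries of the groups do not overlap, the mean reaches 5 FPKM in the higher group and the symbol is not a clone-style name. Where fewer than 6 pass in a direction, genes meeting the other conditions are added up to 6 by the smallest unadjusted p, which here gave all of them. It also takes, for each list described, up to 4 members with the smallest p. Genes of the replicate-number difference were chosen after their values were seen. Enrichment of the table's own pathway terms among called genes was not run because 0 genes were called.

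The tests were run on counts simulated for 18873 genes with the means, depths and dispersions of these libraries, in which 80 well expressed genes were changed 2-fold, 60 changed 4-fold and 60 changed 16-fold. For the comparison of overexpression with wild type, edgeR recovered 1.25% of 2-fold, 25% of 4-fold and 96.7% of 16-fold changes, with 10 false calls. DESeq2 (1.42.0) recovered 1.25%, 58.3% and 100% with 63 false calls. These simulated counts held no difference shared by libraries of the same replicate number, so the rates may not hold for the real libraries. Camera recovered 96% of 50 simulated lists of 37 genes shifted by -0.3 on the log2 scale among 11229 genes simulated as independent. Of the unshifted lists, 2.21% had p under 0.05. Members of real lists can be correlated and can share the difference between replicate numbers, so these rates may not hold for them.

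Alternatives were DESeq2, DESeq2's size factors in edgeR, no low-count filter, the replicate number as a block, limma on FPKM with pseudocounts of 0.1 and 0.5, filters of 0 and 5 FPKM, rescaling, quantile normalization, no trend, a robust prior, and each library left out in turn. For lists, an estimated correlation and fry were added to these. After the data had been seen, counts divided by 4, DESeq2 with a replicate block, camera on log2 CPM, camera with a variance trend and removal of a GC content and transcript length trend were added. GC content and length were taken from GENCODE transcripts, which covered 99.9% of the genes. KEGG terms named in the table were also tested with camera after the data had been seen.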

Results

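Poly(A)-selected RNA of ARP1, an established human multiple myeloma cell line, was sequenced as paired-end libraries from 2 kinds of cells. Multiple myeloma is a cancer of antibody-secreting plasma cells. The cells either overexpressed RFWD2 or were the wild type control, with 2 libraries each. RFWD2 is the older symbol of COP1, which encodes an E3 ubiquitin ligase, an enzyme that marks transcription factors and other proteins for degradation by the proteasome. The series' title and design text set the overexpressing cells against the controls and call the libraries biological repeats. They do not say whether the repeats were separate cultures, so gene p-values measure the spread between these libraries, which may in part be technical. Camera's p-values with the preset correlation instead set a list's members against the other genes, which are not independent replicates. Total estimated counts were 62143098 and 70322496 in overexpression libraries 1 and 2, and 70149131 and 70713792 in wild type libraries 1 and 2. Between 10587 and 11658 genes reached 1 FPKM (fragments scaled to transcript length and to the mapped fragments of the library) in a library.

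The libraries resembled each other more by replicate number than by genotype. Across 11203 genes with a mean of at least 1 FPKM, Pearson's r of log2 CPM (counts scaled to library size) was 0.96 between the overexpression and wild type libraries numbered 1 and 0.97 between those numbered 2. It was 0.90 between the 2 overexpression libraries and 0.93 between the 2 wild type libraries. Genes are not independent replicates, and the values only rank the libraries by likeness. Mitochondrially encoded genes took 7.46% and 7.68% of counts in the overexpression and wild type libraries numbered 1, and 4.96% and 4.27% in those numbered 2. For that reason, values of each library or within each replicate number are given beside pooled ones.

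RFWD2 itself (COP1, ENSG00000143207, minus strand of chromosome 1, 175944831 to 176206691) was measured first. Its FPKM was 13.5 and 13.9 in the overexpression libraries and 5.99 and 8.93 in the wild type libraries, or 13.7 ± 0.33 against 7.46 ± 2.08 (SD, n = 2 each). Both overexpression libraries lay above both controls. The log2 fold change was 0.86 ± 0.36 (SE), with 1.17 within replicate number 1 and 0.55 within replicate number 2. This difference did not pass edgeR's quasi-likelihood test over all genes (Benjamini-Hochberg adjusted p = 1.0). Whether reads of an introduced sequence were counted in this value is not given in the sources used here.

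**Figure D1:**
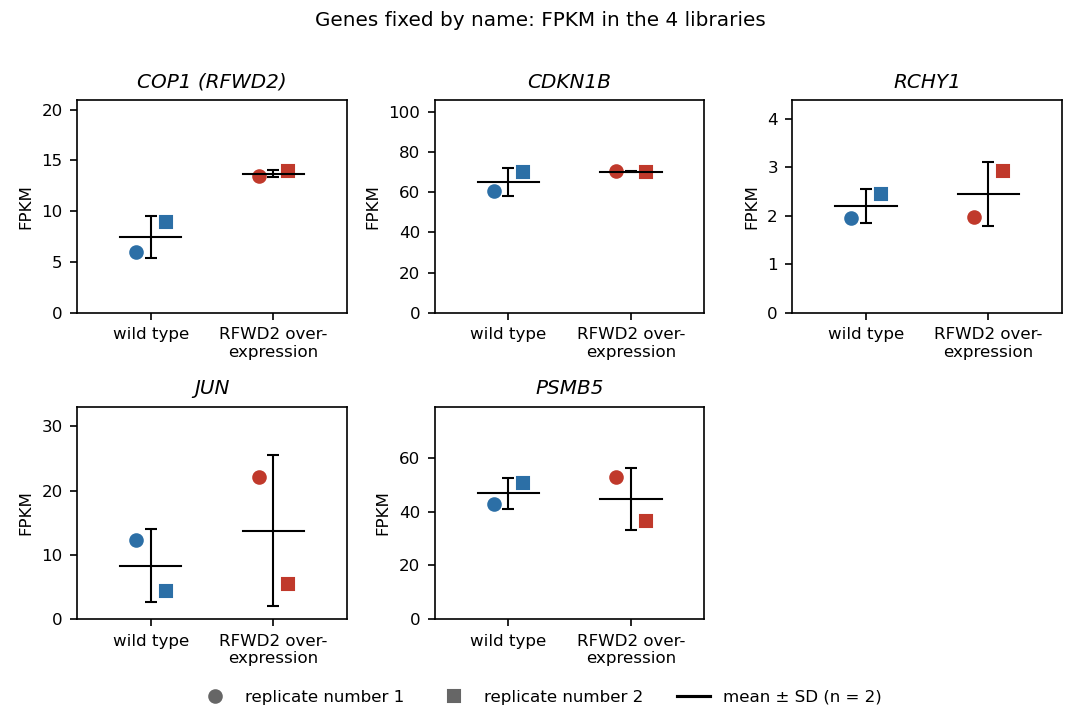
FPKM (vertical axes, linear and starting at 0) of 5 genes fixed by name in wild type (blue) and RFWD2 overexpression (red) libraries, with circles for replicate number 1 and squares for replicate number 2. Horizontal bars and whiskers are the mean ± SD of 2 libraries. COP1 lies at 13.5 and 13.9 FPKM in the overexpression libraries, above 5.99 and 8.93 in the wild type.

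CDKN1B, RCHY1, PSMB5 and JUN, also fixed by name, did not pass the test either. CDKN1B, which encodes the cyclin-dependent kinase inhibitor p27, stood at 70.3 ± 0.32 FPKM with overexpression and 65.3 ± 6.92 in wild type (SD, n = 2 each), a log2 fold change of 0.08 ± 0.32 (SE) that was 0.23 and -0.10 within replicate numbers 1 and 2. RCHY1, another E3 ubiquitin ligase, was at 2.45 ± 0.67 against 2.21 ± 0.35 FPKM (0.02 and 0.16 within the numbers). The proteasome catalytic subunit gene PSMB5 was at 44.6 ± 11.6 against 46.8 ± 5.76 FPKM, higher with overexpression within replicate number 1 (log2 fold change 0.31) and lower within number 2 (-0.58). JUN, whose protein is a known COP1 substrate, had 22.1 and 5.45 FPKM with overexpression and 12.3 and 4.29 FPKM in wild type, or log2 fold changes of 0.84 and 0.25 within the numbers. Fits that leave out a library set unequal mixtures of replicate numbers against each other. In them JUN ran from -0.89 without overexpression library 1 to 1.86 without wild type library 1. CDKN1B changed sign without overexpression library 1 (-0.11), and RCHY1 and PSMB5 did without overexpression library 2 (-0.02 and 0.31). All 4 adjusted p-values were 1.0.

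Over the transcriptome, 18873 genes were tested, and edgeR called 0 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 346 genes, 1.83% of those tested, of which 236 had higher and 110 lower values with overexpression. This is a smaller share than that threshold alone gives where no gene differs, so it is no sign of changed genes. The difference between replicate numbers counts as spread in this test, so the 0 calls do not show unchanged genes either. DESeq2 called 33 higher and 22 lower genes. Of these 55 genes, 30 had a mean under 1 FPKM, 29 had a count of 0 in at least 1 library, and 30 overlapped another gene on the same strand. DESeq2 fitted 28086 genes, and 11229 genes reached that mean, so genes under it were not in excess among the calls. Of the 55 genes, 45 had an unadjusted p under 0.05 with edgeR. Leaving out a library raised edgeR's calls to 144 without overexpression library 1, 183 without overexpression library 2, 73 without wild type library 1 and 83 without wild type library 2. Fold changes within the 2 replicate numbers were only weakly related across genes with a mean of at least 1 FPKM (Pearson's r = 0.07, Spearman's rho = 0.11), and 62 genes were at least 2-fold higher in both, 25 at least 2-fold lower in both and 65 at least 2-fold apart in opposite directions. In 9.55% of those genes both overexpression libraries lay above both controls and in 6.44% both lay below, where exchangeable libraries give 16.7% each way. The libraries here, more alike by replicate number than by genotype, are not exchangeable, so these shares cannot be read against that value.

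Among genes of at least 5 FPKM, those with the smallest unadjusted p and higher values in both overexpression libraries were DEPP1, SLC39A9, HBG2, EHD1, IGFBP4 and HBE1. DEPP1, a FOXO-responsive gene linked to autophagy, was at 33.6 and 31.6 FPKM with overexpression and 4.26 and 4.94 FPKM in wild type, a log2 fold change of 2.80 ± 0.37 (SE, adjusted p = 1.0 with edgeR, 7.6e-06 with DESeq2) that was 2.98 and 2.58 within replicate numbers 1 and 2. DESeq2 called no other of these 6 genes. EHD1, a regulator of endosome recycling, was at 37.3 ± 12.2 against 12.2 ± 0.12 FPKM (SD, n = 2 each), a log2 fold change of 1.91 within number 1 and 1.15 within number 2. IGFBP4, a binding protein of insulin-like growth factors, was at 10.5 ± 3.83 against 3.44 ± 0.91 FPKM (1.47 and 1.59 within the numbers). The zinc transporter gene SLC39A9 was at 10.6 ± 3.14 against 3.07 ± 0.73 FPKM (1.23 and 2.23). The embryonic globin gene HBE1 had 54.9 and 26.2 FPKM against 10.5 and 9.70 FPKM, and the fetal globin gene HBG2 had 8.48 and 4.86 FPKM against 1.48 and 1.21 FPKM. The models of these globin genes overlap each other and further genes on the same strand, so their reads may be shared. Summed over the models overlapping HBG2, the log2 fold change was 1.85, against 2.12 for HBG2 alone.

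The genes with the smallest unadjusted p and lower values in both overexpression libraries were PPAN-P2RY11, CCDC137, MAPK14, CBSL, JPT2 and PSME3. MAPK14, encoding the stress-activated kinase p38 alpha, was at 5.62 ± 1.31 FPKM with overexpression and 15.6 ± 2.83 FPKM in wild type (SD, n = 2 each), a log2 fold change of -1.52 ± 0.33 (SE, edgeR adjusted p = 1.0) that was -1.53 and -1.52 within replicate numbers 1 and 2. PSME3, an activator subunit of the proteasome, was at 16.8 ± 6.31 against 38.3 ± 9.22 FPKM (-1.37 and -1.17 within the numbers). CCDC137 was at 2.77 ± 0.06 against 11.4 ± 2.94 FPKM (-1.76 and -2.34) and JPT2 at 3.38 ± 1.41 against 13.4 ± 5.57 FPKM (-2.84 and -1.20). DESeq2 called PPAN-P2RY11, CCDC137 and JPT2 lower (adjusted p = 3.3e-21, 0.014 and 0.042). CBSL is a near-identical copy of CBS, which encodes cystathionine beta-synthase of the transsulfuration pathway, and the counting could split their reads. CBSL was listed at 0 and 0.21 FPKM with overexpression and at 7.10 and 19.0 FPKM in wild type. The sum of CBS and CBSL was 19.6 and 18.1 FPKM against 31.2 and 33.7 FPKM. The readthrough model PPAN-P2RY11 had 0.17 and 0.18 FPKM against 8.98 and 7.56 FPKM (log2 fold change -5.56 ± 0.52, SE, edgeR adjusted p = 0.88), but summed with the overlapping PPAN and P2RY11 models the locus stood at 16.9 and 22.2 FPKM against 20.9 and 22.3 FPKM.

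Of the 38 gene lists written down, 30 had at least 5 members with a mean of at least 1 FPKM. Camera with its preset correlation placed 11 of them past an adjusted p of 0.05, 5 upwards and 6 downwards. With an estimated correlation it called 0, and the self-contained test fry also called 0 (smallest adjusted p 0.15, for the ATF4 list). Camera with an estimated correlation takes its degrees of freedom from the libraries, 2 here, and no longer from the number of genes. Hardly any list could pass on these, so its adjusted p-values below do not by themselves show correlated members. No member of any list was called by edgeR, either over all genes or adjusted over the list alone. The estimated correlation was 0.75 for S phase, 0.49 for MYC target and for G2 and mitosis, 0.34 for antigen presentation and 0.33 for proteasome genes. It was 0.12 for histone genes and between -0.02 and 0.05 for the other lists past the threshold. These estimates include the difference between replicate numbers. Where they lie far above the preset of 0.01, camera's p-values with the preset are too small. List medians below are of log2(FPKM + 1), which understates the change of low genes.

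Genes of the ATF4 and amino acid response, which supply cells with amino acids and charged tRNAs under stress, fell as a list with RFWD2 overexpression. The median log2 fold change of its 37 members was -0.36, with quartiles of -0.58 and -0.26 (camera adjusted p = 2.5e-13; adjusted p = 0.36 with an estimated correlation). Of the members, 35 were lower within replicate number 1 (median -0.37), 31 within number 2 (median -0.46) and 30 within both, and 12 had both overexpression libraries below both controls. The amino acid transporter gene SLC7A5 was at 51.1 and 74.0 FPKM with overexpression and at 96.9 and 118 FPKM in wild type. The asparagine synthetase gene ASNS was at 16.5 and 20.3 FPKM against 29.2 and 29.9 FPKM. PSAT1, an enzyme of serine synthesis, was at 25.6 and 53.1 FPKM against 50.1 and 91.7 FPKM, and the secreted glycoprotein gene STC2 was at 6.12 and 3.74 FPKM against 9.80 and 9.47 FPKM. These 4 genes had log2 fold changes from -0.97 to -0.74 and edgeR adjusted p-values of 1.0. The list's call was kept without each library in turn (adjusted p from 8.3e-13 to 0.019).

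**Figure D2:**
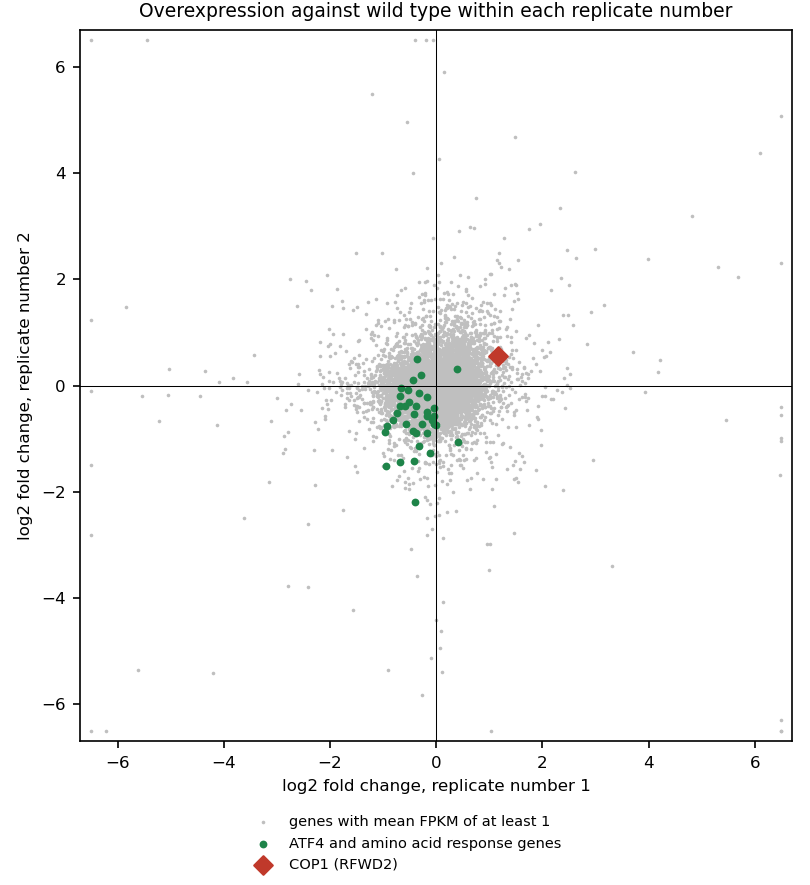
Log2 fold change of RFWD2 overexpression over wild type (log2 CPM) within replicate number 1 (horizontal axis) and number 2 (vertical axis) for 11203 genes with a mean of at least 1 FPKM, grey points, with the ATF4 and amino acid response genes in green and COP1 as a red diamond. The 20 genes beyond 6.5 on an axis are drawn at that limit. Most green points lie in the lower left part, while the grey cloud shows little relation between the axes (r = 0.07).

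The list of MYC target and ribosome biogenesis genes fell as well, as did hypoxia and glycolysis genes and the genes of endoplasmic reticulum (ER) chaperones and the unfolded protein response. MYC targets had a median of -0.22 over 44 members (camera adjusted p = 2.5e-05; adjusted p = 0.81 with an estimated correlation), at -0.31 and -0.14 within replicate numbers 1 and 2, with 31 members lower in both. Of the polyamine synthesis genes, SRM was at 74.1 and 79.9 FPKM with overexpression and 103 and 125 FPKM in wild type, and ODC1 at 184 and 353 FPKM against 294 and 532 FPKM. PPAN went the other way, at 15.4 and 19.7 FPKM against 10.3 and 13.2 FPKM, but its model overlaps PPAN-P2RY11. MYC itself was at 3.44 and 4.48 FPKM with overexpression and at 3.45 and 90.4 FPKM in wild type. Its log2 fold change of -3.51 ± 1.29 (SE) rested on wild type library 2 and was 0.02 without it. The list's median became 0.15 without overexpression library 1 (adjusted p = 0.98) and 0.10 without wild type library 2 (adjusted p = 0.75). Library 2 of each genotype held more of these genes than library 1, by a median of 0.69 with overexpression and 0.60 in wild type on the log2 scale.

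Hypoxia and glycolysis genes had a median of -0.24 over 36 members (camera adjusted p = 2.3e-04; adjusted p = 0.59 with an estimated correlation), at -0.12 within replicate number 1 and -0.30 within number 2, and 17 members were lower in both. Lactate dehydrogenase gene LDHA was at 164 and 200 FPKM with overexpression and 267 and 375 FPKM in wild type, hexokinase gene HK2 at 2.67 and 4.02 FPKM against 5.06 and 8.62 FPKM, and the collagen prolyl hydroxylase gene P4HA1 at 18.9 and 10.3 FPKM against 22.0 and 41.1 FPKM. The glycolytic regulator PFKFB3 went the other way, with 7.11 and 10.5 FPKM against 4.55 and 5.24 FPKM. The call was lost without overexpression library 2 (median -0.04, test direction upwards, adjusted p = 0.94) and without wild type library 1 (median -0.13, adjusted p = 0.14). ER chaperone and unfolded protein response genes had a median of -0.18 over 40 members, at -0.20 and -0.18 within the numbers, with 24 members lower in both (camera adjusted p = 2.1e-03; adjusted p = 0.73 with an estimated correlation). The chaperone gene CALR was at 321 and 377 FPKM against 443 and 484 FPKM, and the disulfide isomerase genes PDIA3 and PDIA4 had log2 fold changes of -0.40 and -0.39. SYVN1, an E3 ligase of ER-associated degradation, was at 12.5 and 8.60 FPKM against 6.54 and 7.01 FPKM. Leaving out any of the 4 libraries ended this call, with adjusted p-values from 0.060 to 0.27. The median was -0.04 without overexpression library 1 and -0.02 without wild type library 2, but -0.25 without overexpression library 2 and -0.29 without wild type library 1.

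NF-kB targets, interferon-stimulated genes and antigen presentation genes rose as lists with RFWD2 overexpression. NF-kB targets had a median of 0.30 over 18 members, at 0.40 and 0.25 within replicate numbers 1 and 2, with 12 members higher in both (camera adjusted p = 4.8e-05; adjusted p = 0.55 with an estimated correlation). The adhesion molecule gene ICAM1 was at 6.97 and 7.63 FPKM with overexpression and 4.73 and 2.42 FPKM in wild type, and the transcription factor gene IRF1 at 9.10 and 6.19 FPKM against 4.83 and 3.68 FPKM. The chemokine gene CXCL10 was high in overexpression library 2 alone, at 16.5 FPKM, with 1.16 FPKM in overexpression library 1 and 0.69 and 1.31 FPKM in wild type. The call ended without overexpression library 1 (median 0.16, adjusted p = 0.084) and without wild type library 2 (median 0.28, adjusted p = 0.13). Interferon-stimulated genes had a median of 0.31 over 16 members, at 0.20 and 0.40 within the numbers, with 10 members higher in both (camera adjusted p = 6.7e-04; adjusted p = 0.55 with an estimated correlation). IRF9, a factor of the interferon response, was at 2.93 and 1.73 FPKM against 1.09 and 0.85 FPKM. PARP9 was at 0.27 and 2.26 FPKM against 0.23 and 0.43 FPKM, and MX2 and HERC6 stayed under 0.12 FPKM in every library. PARP9, MX2 and HERC6 had means under 1 FPKM and were not among the 16 members tested. The call ended without overexpression library 2 (median 0.24, adjusted p = 0.14) and without wild type library 2 (median 0.37, adjusted p = 0.096). Antigen presentation genes had a median of 0.29 over 21 members, at 0.16 and 0.41 within the numbers, with 13 members higher in both (camera adjusted p = 6.7e-04; adjusted p = 0.81 with an estimated correlation). Among the members with the smallest p, HLA-DOA was at 0.68 and 0.31 FPKM against 0.16 and 0.08 FPKM. Its mean under 1 FPKM left it out of the 21 members tested. Also among those with the smallest p, HLA-DMB was at 3.38 and 2.06 FPKM against 1.45 and 1.19 FPKM. HLA-DRB1 was at 12.3 and 7.43 FPKM against 5.92 and 4.66 FPKM, and HLA-DPB1 at 5.79 and 3.29 FPKM against 3.26 and 2.02 FPKM. In both genotypes antigen presentation genes were lower in library 2 than in library 1, by medians of -0.54 with overexpression and -0.50 in wild type. Without overexpression library 1 the list's adjusted p was 0.98 with a median of 0.17, and without wild type library 2 it was 0.59 with a median of -0.02.

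The proliferation lists gave no single direction. S phase and DNA replication genes had a median of -0.08 over 52 members (camera adjusted p = 0.033; adjusted p = 0.81 with an estimated correlation), but it was -0.31 within replicate number 1, where 47 members were lower, and 0.13 within number 2, where 37 were higher. Without overexpression library 1 the list was past the threshold upwards, with a median of 0.48 (adjusted p = 9.0e-04), and without wild type library 2 the median was 0.25 (adjusted p = 0.41). The replication factor gene GINS2 was at 16.9 and 23.9 FPKM with overexpression and 25.1 and 28.4 FPKM in wild type, and CDC45 at 10.2 and 24.3 FPKM against 20.95 and 23.3 FPKM. G2 and mitosis genes had a median of 0.14 over 57 members (camera adjusted p = 0.042; adjusted p = 0.81 with an estimated correlation), at -0.01 and 0.25 within numbers 1 and 2, with 27 members higher in both. The mitotic transcription factor gene FOXM1 was at 15.7 and 43.0 FPKM against 14.1 and 16.6 FPKM, and the spindle gene NUSAP1 at 18.5 and 45.3 FPKM against 18.7 and 21.7 FPKM. Without overexpression library 2 the median was -0.26 (adjusted p = 0.10), and without wild type library 1 it was -0.13 (adjusted p = 0.43). Replication-dependent histone genes had a median of 0.23 over 17 members, at 0.27 and 0.20 within the numbers, with 11 members higher in both (camera adjusted p = 1.1e-03; adjusted p = 0.73 with an estimated correlation). HIST1H1E was at 2.54 and 2.82 FPKM against 1.40 and 0.98 FPKM. Their mRNAs largely lack poly(A) tails, and the libraries were poly(A)-selected. The histone call ended without overexpression library 1 (median 0.08) and without wild type library 2 (median 0.14; adjusted p = 0.98 for each).

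Genes around the COP1 ligase did not pass as a list. COP1 partners had a median of -0.07 over 28 members (camera adjusted p = 0.15). The COP9 signalosome subunit gene COPS7B was at 5.97 and 7.16 FPKM with overexpression and 11.1 and 14.2 FPKM in wild type, and the pseudokinase gene TRIB3 at 6.27 and 5.93 FPKM against 8.40 and 8.03 FPKM. Transcription factors known as COP1 substrates had a median of 0.12 over 10 members (adjusted p = 0.64), with JUNB at 70.1 and 56.4 FPKM against 50.6 and 30.8 FPKM and ETV4 at 15.9 and 16.7 FPKM against 19.6 and 21.2 FPKM. ERK and AP-1 responsive genes had a median of -0.07 over 19 members (adjusted p = 0.70). CDK inhibitors and G1 regulators had a median of -0.01 over 26 members (adjusted p = 0.61), and the kinase gene CDK4 was at 61.4 and 66.4 FPKM against 81.7 and 86.4 FPKM. Proteasome subunits were past the threshold downwards with a small median of -0.06 over 48 members, at -0.12 and -0.07 within the numbers (camera adjusted p = 0.046; adjusted p = 0.81 with an estimated correlation), which became 0.09 without overexpression library 1 and 0.08 without wild type library 2 (adjusted p = 0.98 for each).

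**Figure D3:**
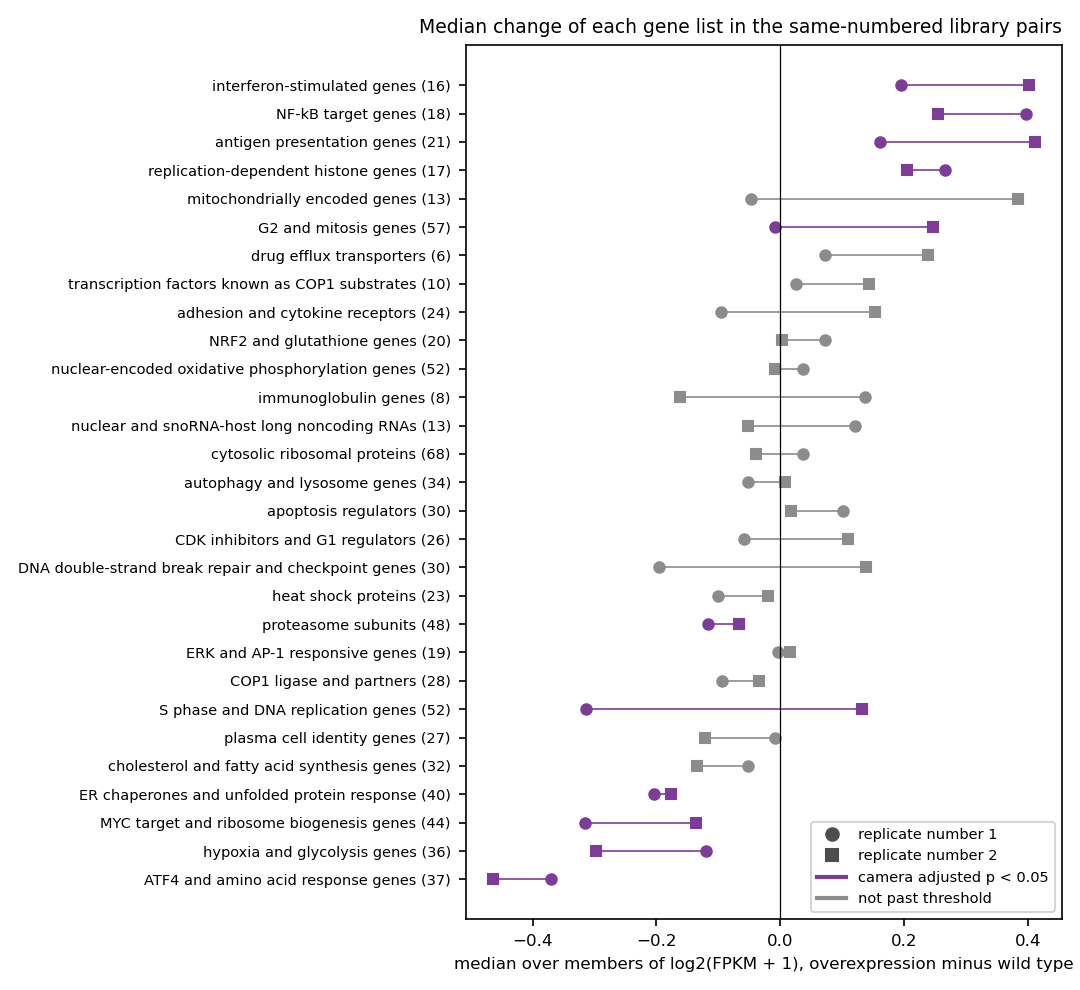
Median over members of the difference in log2(FPKM + 1), RFWD2 overexpression minus wild type (horizontal axis), for each of 29 gene lists with its number of members in parentheses; circles are replicate number 1, squares number 2, and purple marks the 11 lists past a camera adjusted p of 0.05. The ATF4 and amino acid response genes lie lowest, at -0.37 and -0.46, and the S phase list lies on both sides of 0, at -0.31 and 0.13.

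Plasma cell identity genes had a median of -0.08 over 27 members and did not pass (camera adjusted p = 0.46). Within them the kinase gene PIM2 was at 778 and 624 FPKM with overexpression and 391.8 and 415 FPKM in wild type, while the surface receptor gene GPRC5D was at 30.1 and 34.8 FPKM against 69.0 and 49.7 FPKM. Immunoglobulin genes had a median of 0.01 over 8 members (adjusted p = 0.98). Apoptosis regulators did not pass (30 members, adjusted p = 0.70), with the survival gene MCL1 at 160 and 198 FPKM against 115 and 133 FPKM. Heat shock proteins did not pass (23 members, adjusted p = 0.64), and HSPA6 was at 31.5 FPKM in overexpression library 1 and at 1.48 to 2.05 FPKM in the other libraries. Cholesterol and fatty acid synthesis genes (32 members, adjusted p = 0.13), mitochondrially encoded genes (13 members, 0.15), nuclear-encoded oxidative phosphorylation genes (52 members, 0.88), NRF2 and glutathione genes (20 members, 0.73) and autophagy and lysosome genes (34 members, 0.64) did not pass either. Other lists short of the threshold were DNA double-strand break repair and checkpoint genes (30 members, adjusted p = 0.61), cytosolic ribosomal proteins (68 members, 0.70), drug efflux transporters (6 members, 0.62), myeloma adhesion, chemokine and cytokine receptors (24 members, 0.58) and nuclear and snoRNA-host long noncoding RNAs (13 members, 0.97). In 5 lists that did not pass, the median, the mean and camera's direction differed in sign, the largest gap being in heat shock proteins (median -0.05, mean 0.08).

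The 8 lists of markers of other cell types had too few members at 1 FPKM to be tested. The median member stayed at or below 0.13 FPKM in every library for B cell, T and NK cell, myeloid, erythroid and megakaryocyte, fibroblast, endothelial, epithelial and adipocyte markers. Their highest single members were BACH2 among B cell markers, at 2.20 to 4.31 FPKM, HBG2 among erythroid markers, EGFL7 among endothelial markers, at 2.23 to 7.98 FPKM, and PPARG among adipocyte markers, at 5.47 to 6.43 FPKM.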

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

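Alternatives chosen after the data were seen were counts divided by 4, DESeq2 with a replicate block, camera on log2 CPM, camera with a variance trend, and removal of a GC content and length trend.

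RFWD2 was higher with overexpression under all 20 alternatives, with a log2 fold change from 0.70 to 1.03, and was called under none of them (lowest adjusted p 0.16).

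The count of called genes depended on the processing. DESeq2 called 33 genes higher and 22 lower, 55 of them at least 2-fold. Without the low-count filter edgeR called 2 higher and 6 lower, 8 of them at least 2-fold. Leaving out each library in turn gave 49 to 80 higher and 24 to 103 lower genes, with 73 to 183 changed at least 2-fold. In such a fit the lone library of an arm is assumed to vary like the other group, and the difference between replicate numbers in its arm no longer enters the spread. For the other changes the cause was not tested. EdgeR with DESeq2's size factors, edgeR on counts divided by 4 and limma on FPKM under each of its alternatives called 0 genes, with 348, 220 and 38 to 793 genes at an unadjusted p under 0.05.

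The replicate number as a block was an alternative because the labels pair no libraries, and 2 pairs cannot settle it. With it, edgeR's common coefficient of variation fell from 0.505 to 0.341, and 1201 genes (6.36%) had an unadjusted p under 0.05. EdgeR still called 0 genes (lowest adjusted p 0.070), while DESeq2 with the block called 78 higher and 57 lower, 125 of them at least 2-fold. Adjusted over the list alone, edgeR with the block called 6 ATF4, 3 hypoxia and glycolysis and 1 proteasome member, against 0 without it. Of 16 KEGG terms 14 were past the threshold with the block as well. Glycine, serine and threonine metabolism and arachidonic acid metabolism missed it (camera adjusted p = 0.10 each), and aminoacyl-tRNA biosynthesis passed (0.041). On data simulated with such a block, blocked edgeR recovered 41.3% of 2-fold and 98.3% of 4-fold changes, with 29 false calls.

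Camera placed 11 lists past the threshold, but 0 with an estimated correlation and 0 with fry. The estimated correlation leaves camera 2 residual degrees of freedom, on which hardly any list could pass. The other alternatives that keep all libraries gave 9 to 12 lists. The ATF4, MYC target, hypoxia, endoplasmic reticulum, NF-kB, interferon, antigen presentation and histone lists kept their call and direction in all 10 of these. S phase and G2 and mitosis genes kept theirs in 6 and proteasome subunits in 4. Leaving out a library gave 5 to 11 lists, with 5 without wild type library 2, and among the 11 lists the ATF4 list alone kept its call and direction in all 4 such fits.

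Leaving out a library reversed camera's direction, with a call before or after, in 10 lists. Over the 4 such fits the medians ran from -0.61 to 0.48 for S phase genes, -0.42 to 0.40 for DNA double-strand break repair, -0.31 to 0.094 for proteasome subunits, -0.019 to 0.66 for antigen presentation and -0.27 to 0.23 for immunoglobulins. They ran from -0.26 to 0.54 for G2 and mitosis, -0.28 to -0.042 for hypoxia and glycolysis, -0.22 to 0.25 for cytosolic ribosomal proteins, -0.35 to 0.64 for mitochondrially encoded genes and 0.078 to 0.37 for histones. The reversals came without overexpression library 1 for S phase, repair, proteasome, antigen presentation, immunoglobulin and histone genes. Without overexpression library 2 they were G2 and mitosis, hypoxia and ribosomal protein genes. Without wild type library 1 they were G2 and mitosis and ribosomal protein genes, and without wild type library 2 S phase, antigen presentation and mitochondrially encoded genes. The median alone turned positive for MYC targets without overexpression library 1 (0.15) or wild type library 2 (0.10) and for proteasome subunits without wild type library 2 (0.076). Such a fit sets unequal mixtures of replicate numbers against each other, so the difference between the numbers enters the fold change. Over all lists and alternatives camera's or fry's direction changed in 59 of 479 values, and for named genes the fold change did in 32 of 2391.

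DESeq2, its size factors and limma's robust and trendless priors were not run for lists. A mean of at least 5 FPKM left 29 lists to test. In the simulation without a block, at the depth of these libraries, edgeR recovered 1.25% of 2-fold and 96.7% of 16-fold changes.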

Other observations

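Tests chosen only after the result was seen were those of depth, of single lists against GC content, of the ATF4 list within each replicate number, of genes and lists between the replicate numbers, and of KEGG terms.

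The difference between replicate numbers, taken over both genotypes with edgeR and genotype in the model, covered 1359 genes, of which 558 were higher and 801 lower in the libraries numbered 2. DDIT4, ZFP36 and HSPA1A were among the lower ones, named after their values were seen. DDIT4, an inhibitor of mTORC1, was at 206 and 400 FPKM in overexpression and wild type library 1 and at 22.4 and 60.5 FPKM in library 2. The mRNA-decay factor gene ZFP36 was at 53.5 and 37.4 FPKM against 9.48 and 6.95 FPKM, and the heat shock gene HSPA1A at 191 and 79.6 FPKM against 29.5 and 21.02 FPKM, while heat shock proteins as a list did not pass (median 0.47 on the log2 scale, number 2 minus number 1, camera adjusted p = 0.66). The translation factor gene EIF4G2 went the other way, from 9.60 and 17.6 FPKM in library 1 to 49.1 and 58.9 FPKM in library 2. Each of these had an adjusted p of 0.048.

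Of the 30 gene lists, 13 were past camera's threshold for the difference between replicate numbers, and 0 were with an estimated correlation. S phase genes had a median of 0.89 on the log2 scale (number 2 minus number 1, camera adjusted p = 1.2e-06), G2 and mitosis genes 0.71, MYC target genes 0.74 and cytosolic ribosomal proteins -0.43 (camera adjusted p = 1.3e-14). The estimated correlation gave an adjusted p of 0.72 for these lists. With genotype in the model that test rests on 1 residual degree of freedom. Practically no list could pass on it, so no conclusion is drawn from its 0 calls. Mitochondrially encoded genes were at -0.72, antigen presentation genes at -0.48 and DNA repair genes at 0.79. The number difference ran against GC content across genes (rho = -0.67), and with a GC content and length trend removed 13 lists were past the threshold, 10 of them also before and in the same direction. The medians of S phase, G2 and mitosis and DNA repair genes were then 0.42, 0.21 and 0.16.

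Camera over 285 KEGG terms between the genotypes gave 16 past the threshold, 13 upwards and 3 downwards, and 0 with an estimated correlation. The latter again rested on 2 residual degrees of freedom, on which hardly any term could pass. The term for Staphylococcus aureus infection led (16 genes, median 0.53, camera adjusted p = 1.1e-07; adjusted p = 0.99 with an estimated correlation). Ribosome biogenesis in eukaryotes (72 genes, median -0.08) and glycine, serine and threonine metabolism (21 genes, median -0.07) were among those that fell. Their camera adjusted p-values were 0.038 and 0.030, and 0.99 for each with an estimated correlation. Their medians were -0.14 and -0.11 within replicate number 1 and -0.03 and -0.06 within number 2.

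Libraries separated by replicate number, with deviations related between the genotypes across 11203 genes (r = 0.59), and the labels do not say whether equal numbers share a day, a culture or a preparation. Depth is argued against, since the 2 wild type totals differed by a ratio of 1.01. Large shares of the cell types in the marker lists are argued against too, since the highest median of a marker list in a library was 0.127 FPKM. Those lists could not detect other plasma or myeloma cells. Removing a GC content and length trend lowered the correlation of the genotypes' number differences from 0.66 to 0.471, between the bounds set in advance. After removal the medians were -0.60 for ribosomal protein, -0.952 for mitochondrially encoded, -0.660 for antigen presentation and 0.609 for MYC target genes. These values argue against that trend as the whole cause. S phase genes, at 0.42, and G2 and mitosis genes, at 0.21 and only just, met the bounds set for MYC target genes after the result was seen. DNA repair genes, at 0.16, did not. MYC target, S phase, G2 and mitosis and DNA repair genes all moved closer to 0 and stay open to the trend in part. The design gives no group for the numbers, so no biological explanation was tested.

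The lower ATF4 list was weighed as well. Its median of -0.36 was -0.367 after the part predicted by the number difference was removed. Each genotype holds both replicate numbers, and the list's own number difference was small (median -0.06). That removal could therefore hardly move the median, and no conclusion is drawn from it. The median was -0.390 after a GC content and length trend was removed, and at least 83.8% of members were lower within each replicate number. These values argue against that trend and against a single replicate number as the whole cause. These tests bear on technical explanations only. The overexpression itself and a difference between cultures in nutrients or density at harvest were not told apart by any test and stay open. The list was called by camera with its preset correlation alone, not with an estimated one or with fry. Its estimated correlation was -0.016, under the preset of 0.01, yet camera's unadjusted p went from 8.2e-15 to 0.012. The loss of that call therefore does not show correlated members. It goes with the 2 residual degrees of freedom of that test, which cannot decide for or against the list.

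Overlapping gene models were the last pattern weighed. Of 75 genes with an unadjusted p under 0.01, 39 (52.0%) overlapped another gene on the same strand, against 33.0% of the others (Fisher's exact test, two-sided, odds ratio 2.20, p = 7.95e-04, genes not being independent). Summing counts over the overlapping models lowered the median absolute log2 fold change of the 39 genes from 2.71 to 0.691, a ratio of 0.255. Reads split unevenly between models would give such a drop. The genes were chosen by a small p, however, and a sum also dilutes a real change of a low gene beside an abundant neighbour. The drop cannot tell these apart, and both stay open.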
